A study of Mus musculus with 14 samples.

How the data were processed

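Total RNA of sorted mouse splenic B cells was amplified, labelled with biotin and hybridised to Affymetrix arrays, 14 in all. Per the labels every sort excluded cells positive for CD11b, Ter119, Gr-1, CD3, CD4, CD8 or CD5. Naive cells were gated on B220, CD23, low IgM, IgD and the lambda light chain. The immunized subsets bound NP and were gated on syndecan-1 (plasma cells), PNA with low CD38 (germinal center cells), or high CD38 without IgM, IgD or PNA (memory cells). The dose was 100 µg for every immunized array except plasma replicate 1, whose label gives none.

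The deposited table holds 1 intensity per probe set and array. The submitters' processing notes name RMA without a version, chip definition or software. All values lay above 0 on a linear scale, so log2 was taken with no pseudocount and no further scaling. The table has 45101 probe sets, of which 64 are controls. Of the 45037 others, 34945 carry 1 gene symbol, 932 several and 9160 none. Symbols were checked through the Entrez number against the reference gene table, which matched 34741 probe sets and changed 0 symbols. Each of 18193 genes was represented by its brightest probe set with a single symbol, and 9010 genes had more than 1. Probe sets with several symbols or none entered no gene count. The background of an array was the brightest of 27 bacterial control probe sets that were not spiked in, between 11.0 and 16.1.

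The design, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from 3 alternatives, 2 patterns of shared genes, the tests of Hbb-bh1, the interferon list and Mki67, and the naming of Nid1, Cd80 and Pdcd1lg2 among genes of memory cells, all added afterwards. Linear models were fitted with limma 3.58.1 in R 4.3.3 on all 14 arrays with 1 mean per subset and 10 residual degrees of freedom. Moderated statistics came from eBayes without a trend. Every test was two-sided. The p-values were adjusted by Benjamini-Hochberg within each of 6 contrasts. A gene was called at an adjusted p under 0.05. Gene lists were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over 29 lists and 6 contrasts (174 tests). They were compared again with the correlation estimated for each list. Where a list passed both ways, mostly the preset p-value is printed, and the other can be many orders of magnitude larger. A list needed 5 measured genes. The list of immunoglobulin constant regions, 1 of 30, had fewer and was left out, and its genes were described singly. A gene set 1 subset or pair of subsets apart when it passed with a log2 fold change of at least 1 in each contrast concerned. A fold was given only as a bound where the lower subset lay above background on no array, which held for 35 of 234 named folds. In 51 others the lower subset lay above it on some arrays only. In naive cells that was 1 of 3 arrays for Mki67, Cdca5, Rgs13, Jchain, Tent5c, Prdm1, Bhlha15, Sspn and Lmo7, and 2 of 3 for Eaf2, Hemgn, Ighg3, Bst2, Fscn1, Bmpr1a, Parm1 and Tk1. In germinal center cells it was 1 of 3 for Klf3, Tsc22d1 and Ccr7, and 2 of 3 for Irgm1, Gpr183 and Selplg. In memory cells it was 1 of 4 for Sdc1 and Ccnb2, 2 of 4 for Ncapg, Rgs13 and Rad51ap1, and 3 of 4 for Fkbp11. In plasma cells it was 1 of 4 for Serpinb1a, 2 of 4 for Bcl2, Fcer2a, Spib, Cxcr5 and Nid1, and 3 of 4 for Cd40. Principal components were computed on centred log2 values.

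Genes were named by rule. For the 4 main contrasts these were the 6 highest and 6 lowest called genes whose arrays did not overlap. For the contrasts of plasma with germinal center and with memory cells they were the 3 highest and 3 lowest. Immunoglobulin genes and placeholder symbols were left out. Up to 4 of the largest called members of each described list and members against the list were added, with a fixed set of surface markers and regulators and the 6 leading genes of each set apart. The report gives some of these. Values of 2 subsets did not overlap for any named fold that passed, except Csf1r in plasma against naive and Ddit3 in plasma against memory cells.

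The fit was tested on simulated data. Among 18193 genes, 67 per contrast were changed at a log2 fold change of 1. Of these 79.1% were recovered for germinal center, 71.6% for plasma and 82.1% for memory against naive cells. At 2 the shares were 97.0%, 95.5% and 98.5%. Over all simulated sizes together, 5.16%, 3.26% and 4.59% of the calls were false. The simulated values were normal and independent between genes, with few genes changed, so these shares may not hold for the real contrasts. Alternatives to the normalization, filter, gene unit, variance model, arrays, log scale and threshold were run for the counts and named genes where they applied. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.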

Results

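Gene expression was measured on 14 arrays of amplified RNA from B cell subsets sorted from the spleens of male C57Bl/Ka mice. The subsets were naive B cells of unimmunized mice (3 arrays), and antigen-binding cells of mice immunized with the hapten protein NP-CGG in alum: plasma cells at day 7 (4 arrays), germinal center cells at day 14 (3 arrays) and memory cells at 10 to 12 weeks (4 arrays). Nothing in the labels says that replicates came from separate animals, so each p-value measures only the spread between these samples, which may be technical. Age rose with the time after immunization, from 4 to 8 weeks in naive mice to 14 to 18 weeks in the mice that gave memory cells. Between 52.7% and 66.9% of 18193 genes lay above the brightest unspiked bacterial control of their array, and the number of arrays limits the precision of every value. Fold changes are log2 values with their standard errors. Where no array of the lower subset lay above that background, the fold over the background is given as "at least N-fold". For 51 of 234 named folds the lower subset lay above it on some arrays only, and such a fold is printed as fitted.

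The 14 arrays fell into 3 clusters on the first 2 principal components. Component 1 held 54.2% of the variance and set plasma cells apart. Component 2 held 21.4% and set germinal center cells apart. Memory arrays lay beside naive arrays on both, and component 3, with 7.65% of the variance, set them apart. The fewest genes were called between memory and naive cells (1014 of 18193), and the most between plasma and memory cells (6035). Among 6116 genes with a mean log2 value of at least 6, the median change from naive cells was -0.20 in germinal center, -0.25 in plasma and -0.21 in memory cells. A change of a bright gene below that size is within this shift. The balance of directions depended on scaling. Of the genes called in germinal center, plasma and memory against naive cells, 43%, 46.8% and 41.5% were higher, but 57.6%, 67.4% and 68.2% with each array centred on bright genes, an alternative chosen after the data were seen. Quantile normalization gave 55.2% in memory against naive cells. In germinal center against naive cells the share was 33.1% with arrays centred on their median and 53.1% with the actin ratio as a covariate.

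**Figure D1:**
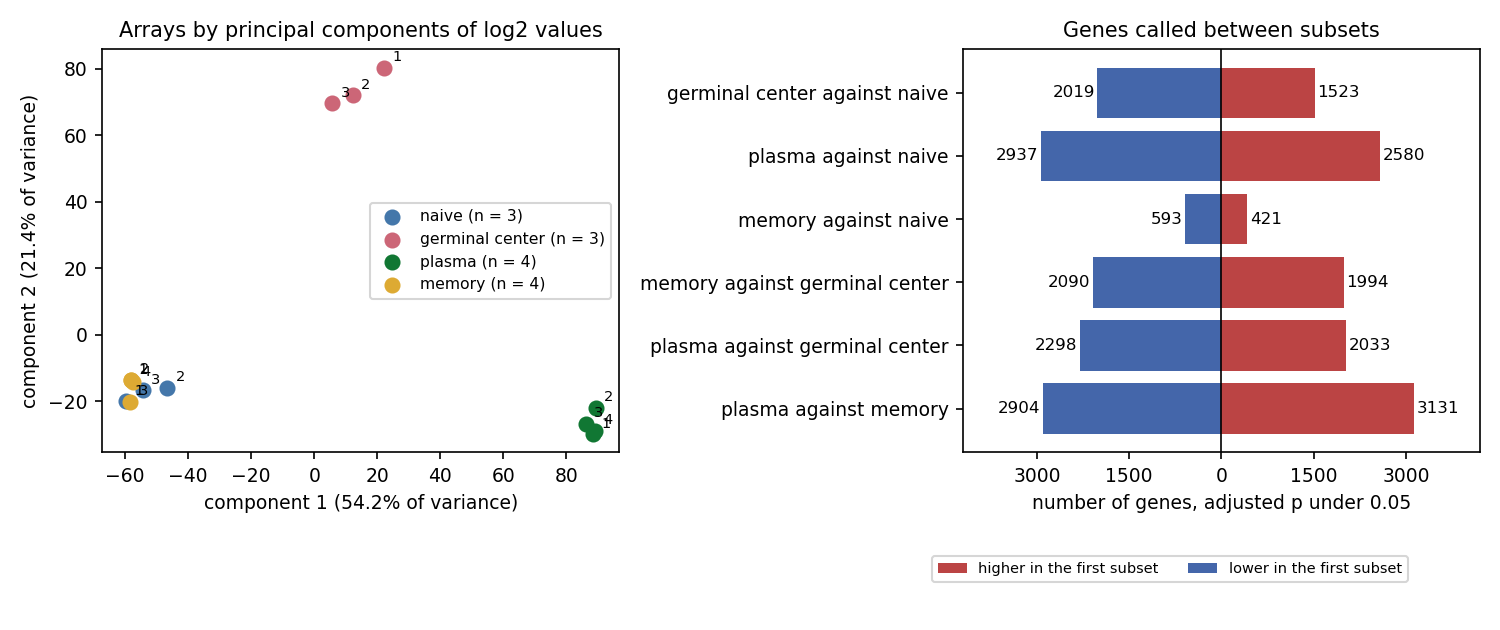
Left, the 14 arrays on the first principal components of their log2 intensities, coloured by subset and numbered by replicate. Right, numbers of genes called at an adjusted p under 0.05 in each of 6 comparisons, from 421 higher and 593 lower in memory than in naive cells to 3131 higher and 2904 lower in plasma than in memory cells.

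The comparison of germinal center with naive cells asked what changed in B cells that divide and mutate their receptors 2 weeks after antigen. Mki67, a marker of dividing cells, rose by 8.88 ± 0.36 (n = 3 and 3, adjusted p = 6.98e-10, limma), from an intensity of 14.6 to 6850. Cdca5 and Ncapg, which act on mitotic chromosomes, rose by 8.48 ± 0.33 and at least 146-fold. Rgs13, which dampens chemokine receptor signals, rose by 7.21 ± 0.28, and the receptor S1pr2, which holds cells in the follicle, by 4.39 ± 0.24. The transcription elongation factor gene Eaf2 rose by 6.96 ± 0.36 and the complement response gene Rgcc at least 79.0-fold. The quiescence factor Klf3 had the largest fall (-7.57 ± 0.27), followed by the actin-binding Cnn3 (-7.46 ± 0.31) and the complement regulator Cd55 (-6.48 ± 0.35). Next were Serpinb1a (-6.44 ± 0.35), Tsc22d1 (-6.35 ± 0.56) and the homeobox gene Hhex (-6.22 ± 0.41). Bcl2, which blocks cell death, fell from 620.0 to 33.7 (-4.20 ± 0.46, adjusted p = 1.15e-05), while the death receptor Fas rose by 3.55 ± 0.32. Bcl6, the repressor that directs germinal centers, rose by only 0.84 ± 0.26 (adjusted p = 0.031), from a level of 1410 in naive cells, and this call was lost without naive array 1 or 2 or germinal center array 2 or 3. Irf4 fell by 3.46 ± 0.33 and Fcer2a, the CD23 on which only naive cells were sorted, by 2.74 ± 0.33. Bach2 did not pass (0.88 ± 0.37, adjusted p = 0.12), and Ptprc, the gene of CD45, of which B220 is an isoform, fell by 0.54 ± 0.18 (adjusted p = 0.0488), a call lost without most single arrays.

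Cell cycle genes moved almost as a block. Of 41 measured mitosis genes 40 rose, among them Ccnb2 (at least 82.6-fold). The list median was 4.51 (camera adjusted p = 2.78e-45, and adjusted p = 0.00642 with an estimated correlation). Of 36 S phase genes 32 rose, Cdc6 at least 56.6-fold and Rrm2 by 6.15 ± 0.46. The S phase median was 2.13 (adjusted p = 1.77e-27, and adjusted p = 0.00642 with an estimated correlation). Adjusted over the list alone, 40 mitosis and 34 S phase genes rose. Of 34 genes of somatic mutation and DNA repair 19 rose and 1 fell (21 and 1 adjusted over the list alone; list adjusted p = 9.03e-11), with Rad51ap1 at 5.41 ± 0.37 and the checkpoint kinase Chek1 at 5.32 ± 0.20. The germinal center identity list rose in 15 of 22 members (15 adjusted over the list alone; list adjusted p = 2.43e-12), led by Rgs13, Basp1 (6.81 ± 0.25) and Gcsam (at least 51.0-fold), with Lmo2 (-1.13 ± 0.24) and Itga6 (-0.64 ± 0.20) against it. Quiescence genes fell in 15 of 28 members (19 adjusted over the list alone), among them Klf2 (-4.74 ± 0.32) and Txnip (-3.22 ± 0.21), while the inhibitor Cdkn2c rose by 2.34 ± 0.18. That list had an adjusted p = 3.67e-09, and adjusted p = 0.0553 with an estimated correlation.

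Genes of the resting B cell fell in the same comparison. Of 26 mature B cell identity genes 17 fell and 0 rose (20 and 2 adjusted over the list alone; camera adjusted p = 8.98e-11), for example Foxp1 (-2.61 ± 0.28) and Cd72 (-2.56 ± 0.18). Of 33 interferon response genes 23 fell and 0 rose (27 and 0 adjusted over the list alone; list adjusted p = 6.96e-15), with Irgm1 at -4.06 ± 0.21, Rtp4 at -3.63 ± 0.24 and the RNA sensor Ddx58 at -3.32 ± 0.15. Chemotaxis and adhesion genes fell in 12 of 26 members, among them Gpr183 (-5.68 ± 0.23), Ccr6 (-5.07 ± 0.26) and Ccr7 (-4.44 ± 0.33), whereas S1pr2 and S1pr3 (3.29 ± 0.27) rose. The counts adjusted over the list alone were the same, and the list's adjusted p = 0.000178 became adjusted p = 0.0967 with an estimated correlation. B cell receptor signalling fell in 18 of 30 members (20 adjusted over the list alone; list adjusted p = 3.67e-09). Toll-like receptor signalling fell in 9 of 20 (12 down and 2 up adjusted over the list alone; list adjusted p = 0.000115), with Irak3 at least 9.85-fold lower. Autophagy and lysosome genes fell in 9 of 27 and rose in 1 (14 and 1 adjusted over the list alone; list adjusted p = 3.78e-06), with Psap at -2.65 ± 0.24. MHC class II presentation fell in 7 of 15 members, H2-Ab1 by 1.39 ± 0.22, while the costimulator Cd86 rose by 2.61 ± 0.20 (8 and 1 adjusted over the list alone). With the 3' to middle actin ratio as a covariate H2-Ab1 did not pass (-0.65, adjusted p = 0.105). The list's adjusted p = 0.00086 became adjusted p = 0.0967 with an estimated correlation.

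Smaller list shifts between germinal center and naive cells rested on the preset correlation. Oxidative phosphorylation genes rose in 15 of 40 members, with Cox6c at 1.63 ± 0.28, and this list had adjusted p = 0.000515, or adjusted p = 0.315 with an estimated correlation. Protein secretion genes fell in 11 of 57 members and rose in 1, with the chaperone Hsp90b1 at -2.97 ± 0.45 (list adjusted p = 0.00117, and adjusted p = 0.372 with an estimated correlation). Immediate early genes fell in 10 of 32 members, with Egr3 at -3.33 ± 0.71 (list adjusted p = 0.00336, and adjusted p = 0.509 with an estimated correlation). Adjusted over the list alone, 17 oxidative phosphorylation genes rose, 11 secretion genes fell and 1 rose, and 10 immediate early genes fell. The methyltransferase gene Ezh2 rose by 3.14 ± 0.22, and Jchain, which joins secreted antibodies, by 7.34 ± 0.73. In all, 1523 genes rose and 2019 fell at an adjusted p under 0.05 in limma, 2256 of them at least 2-fold. The ratio of 3' to middle beta-actin signal, a measure of RNA integrity and labelling length, was 11.3 ± 5.8 in germinal center and 4.79 ± 0.46 in naive arrays (SD, n = 3 each) and so differed along with the subset. The same ratio for GAPDH was no higher in germinal center (9.40 ± 1.3) than in naive arrays (10.6 ± 1.3). The actin ratio itself ran from 6.11 to 17.55 over the germinal center arrays. With this ratio as a covariate, an alternative chosen after the data were seen, Cox6c (1.30, adjusted p = 0.0846), Hsp90b1 (-2.28, adjusted p = 0.0532) and Egr3 (-1.96, adjusted p = 0.359) did not pass. Neither did Lmo2 (-0.69, adjusted p = 0.317), Itga6 (-0.43, adjusted p = 0.572), Bcl6 (1.03, adjusted p = 0.17) or Ptprc (-0.10, adjusted p = 0.912).

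The comparison of plasma with naive cells addressed the change to antibody secretion. Jchain rose by 10.28 ± 0.68 and the constant region genes Igha and Ighg3 by 10.15 ± 0.29 and 9.52 ± 0.25, while Ighm rose by 1.43 ± 0.33 (n = 4 and 3, adjusted p = 0.0043, limma). Prdm1, the repressor that drives plasma cell fate, rose from 10.9 to 520.6 (5.58 ± 0.21, adjusted p = 1.55e-10). Its partner factors Xbp1 and Irf4 rose by 2.58 ± 0.28 and 2.19 ± 0.31, and Sdc1, the surface marker on which these cells were sorted, by 4.22 ± 0.55. Outside the antibody genes the largest rises were in Tent5c, a poly(A) polymerase gene (8.88 ± 0.36), and Mki67 (8.64 ± 0.34). They were followed by Eaf2 (7.89 ± 0.34), Cdca5 (7.69 ± 0.31), the protease inhibitor Slpi (7.54 ± 0.26) and Rgcc (at least 80.4-fold). Cnn3 fell by 8.53 ± 0.29, Hhex at least 267-fold, Ms4a4c at least 124-fold, Serpinb1a by 7.77 ± 0.33, the kinase gene Srpk3 by 7.74 ± 0.26 and the ubiquitin ligase gene Marchf1 at least 131-fold. Bcl6 and Bach2, repressors that oppose plasma cell fate, fell to background from 1410 and 982.9 (at least 103-fold and 71.6-fold). Fcer2a fell by 6.96 ± 0.31, Bcl2 by 5.55 ± 0.43, Ciita, the master regulator of MHC class II, at least 5.58-fold, and Ptprc by 1.28 ± 0.17.

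Secretion genes rose nearly together. Of 57 genes of ER stress and protein secretion 54 rose, Fkbp11 by 5.29 ± 0.25, Derl3 by 5.26 ± 0.26 and Sec24d by 5.25 ± 0.27, and 1, the stress factor Ddit3, fell (-1.31 ± 0.29). The list median was 2.32 (camera adjusted p = 1.17e-29, and adjusted p = 0.00687 with an estimated correlation). Adjusted over the list alone 54 rose and 2 fell. Plasma cell identity genes rose in 16 of 19 members (16 adjusted over the list alone; list adjusted p = 4.65e-13), with Cd28 at least 62.0-fold higher and the secretory factor Bhlha15 at 6.43 ± 0.23. All 26 mature B cell identity genes fell (26 adjusted over the list alone; list adjusted p = 6.79e-28), Cd22 by 7.34 ± 0.22 and the factor Spib by 7.10 ± 0.28. MHC class II presentation fell in 12 of 15 members (13 adjusted over the list alone; list adjusted p = 5.8e-13), with Cd40 at -6.86 ± 0.34 and H2-Ob at -6.67 ± 0.22. B cell receptor signalling fell in 20 of 30 members and rose in 2 (21 and 3 adjusted over the list alone; list adjusted p = 1.29e-11). Toll-like receptor signalling fell in 10 of 20 and rose in 1 (11 and 2 adjusted over the list alone; list adjusted p = 9.68e-06), with Tlr1 at least 68.1-fold lower.

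These plasma cells also carried the transcripts of dividing cells. Of 41 mitosis genes 38 rose (38 adjusted over the list alone; camera adjusted p = 7.97e-31). Of 36 S phase genes 32 rose (32 adjusted over the list alone; list adjusted p = 6.19e-16), with Rrm2 at 6.61 ± 0.43 and the polymerase gene Pold1 against the list (-3.28 ± 0.24). Quiescence genes fell in 16 of 28 members and rose in 3 (17 and 4 adjusted over the list alone), with Btg1 at -5.94 ± 0.28, and the list's adjusted p = 2.67e-05 became adjusted p = 0.163 with an estimated correlation. DNA repair genes rose in 17 of 34 members and fell in 6 (18 and 6 adjusted over the list alone), with an adjusted p = 0.00183, and adjusted p = 0.252 with an estimated correlation. Oxidative phosphorylation rose in 17 of 40 members and fell in 2 (23 and 2 adjusted over the list alone), for example Uqcrq (1.96 ± 0.26), with an adjusted p = 0.000113, and adjusted p = 0.281 with an estimated correlation. Interferon response genes fell in 20 of 33 members, Ifit2 at least 17.1-fold, and rose in 5, such as Bst2 (2.07 ± 0.24), or 22 and 6 adjusted over the list alone. The list's adjusted p = 4.21e-05 became adjusted p = 0.0653 with an estimated correlation. Immediate early genes fell in 13 of 32 members (13 adjusted over the list alone), with an adjusted p = 0.000262, and adjusted p = 0.383 with an estimated correlation. Chemotaxis genes went both ways, 10 up and 11 down of 26 (11 and 11 adjusted over the list alone), with the inflammatory receptor Cxcr3 at 3.99 ± 0.38, Cd44 at 2.77 ± 0.25 and the follicle receptor Cxcr5 at -6.79 ± 0.33. Their median of 0.29, mean of -0.54 and downward test differed in sign (adjusted p = 0.481), as did the median of 0.52 and mean of -0.08 of the germinal center list, whose test pointed up (adjusted p = 0.837).

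Across all genes 2580 rose and 2937 fell in plasma cells against naive cells, 3393 of them at least 2-fold. Myeloid marker genes rose in 9 of 27 members and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.036, and adjusted p = 0.489 with an estimated correlation). Csf1r reached 71.9 (1.30 ± 0.38, with overlapping arrays) and Cd68 20.5 in plasma cells, although the sort excluded CD11b-positive cells. With a floor of 16 neither passed (Csf1r 1.30, adjusted p = 0.0502; Cd68 0.35, adjusted p = 0.171).

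Memory cells were compared with naive cells to find what the resting, antigen-experienced state retained. The actin-bundling gene Fscn1 rose by 6.52 ± 0.53 (n = 4 and 3, adjusted p = 5.72e-06, limma), Sspn by 6.48 ± 0.39, the chemokine-scavenging receptor Ackr2 by 5.40 ± 0.25, the semaphorin Sema4f at least 20.6-fold, Lmo7 by 4.46 ± 0.38 and the annexin Anxa2 by 4.41 ± 0.39. The catenin gene Ctnna1 fell by 3.99 ± 0.51, Ms4a4c by 3.85 ± 0.51, Tsc22d1 by 3.71 ± 0.52, Sdc1 by 3.61 ± 0.55, Gpat3 by 3.61 ± 0.21 and Selenop by 3.56 ± 0.52. Among single genes, Igha rose from 16.2 to 245.9 (3.92 ± 0.29), Ighg3 by 4.14 ± 0.25, Jchain by 2.98 ± 0.68 and Prdm1 by 0.89 ± 0.21 (adjusted p = 0.0251), with memory array 4 at 489.2 for Jchain against 28.5 to 86.3 on the other memory arrays. Memory cells were sorted without IgM or IgD and naive cells on low IgM and IgD, so the rises of Igha and Ighg3 may follow from the gates. The plasma cell identity list did not pass (4 of 19 members rose and 1 fell, adjusted p = 0.0804). With a floor of 16 before log2, Jchain and Prdm1 did not pass (adjusted p = 0.16 and 0.382). Mki67 rose by 3.97 ± 0.34 to 228.8, far below the 6850 of germinal center cells, while 37 of 41 mitosis genes did not pass. Fas rose by 1.81 ± 0.29, Bcl6 fell by 1.85 ± 0.24 to 391.3, and Fcer2a fell by 1.25 ± 0.31. The Fcer2a call was lost in 5 of the fits without 1 array. Bcl2 (1.18 ± 0.43, adjusted p = 0.146) and Bach2 (-0.77 ± 0.35, adjusted p = 0.261) did not pass. As the mean over its probe sets, Bcl2 did pass (0.67, adjusted p = 0.0387).

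Known memory B cell markers rose in 12 of 21 members and fell in 0 (15 and 1 adjusted over the list alone), with a list median of 0.96 (camera adjusted p = 2.88e-18). Among them were the receptor kinase Bmpr1a (4.02 ± 0.26), Parm1 (3.95 ± 0.34) and Nt5e, the CD73 ectoenzyme (at least 7.36-fold). Cd86, of the MHC class II list, rose by 2.68 ± 0.19. Marginal zone and B1 cell markers rose in 5 of 17 members (7 adjusted over the list alone; list adjusted p = 5.3e-08), with S1pr3 at 3.80 ± 0.26, Asb2 at 2.79 ± 0.41 and Spn at 1.85 ± 0.28. Only these 2 lists passed with an estimated correlation as well. Naive but not memory cells were sorted on CD23, and whether that gate shapes the marginal zone and B1 list was not tested. Germinal center identity genes rose in 5 of 22 members and fell in 2 (7 and 3 adjusted over the list alone), with Basp1 at 4.04 ± 0.23 and the glycosylase Neil1 at 3.09 ± 0.35, for an adjusted p = 0.00183, and adjusted p = 0.116 with an estimated correlation. Zbtb20, a factor of long-lived plasma cells, rose by 4.41 ± 0.37. Chemotaxis and adhesion genes rose in 5 of 26 members and fell in 2 (6 and 4 adjusted over the list alone), with Cxcr3 at 3.58 ± 0.38, for an adjusted p = 0.0163, and adjusted p = 0.282 with an estimated correlation.

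Several lists were lower in memory than in naive cells. Bright genes as a whole were also lower, with a median of -0.205 against -0.034 over all genes. Only the interferon list was compared with genes of matched level. How much of the other falls that shift makes up was not tested. Interferon response fell in 6 of 33 members and rose in 0 (12 and 0 adjusted over the list alone), Rtp4 by 2.72 ± 0.22 and Ifit2 by 1.95 ± 0.39, with a median of -0.35 (adjusted p = 2.12e-05, and adjusted p = 0.0553 with an estimated correlation). S phase genes fell in 8 of 36 members (10 adjusted over the list alone), Mcm5 by 1.60 ± 0.20, while Tk1 rose by 1.79 ± 0.31 (list adjusted p = 0.000298, and adjusted p = 0.282 with an estimated correlation). Of the mitosis list, Ndc80 fell by 1.91 ± 0.26. Oxidative phosphorylation fell in 2 of 40 members, Uqcrc1 by 0.94 ± 0.21 and Atp5a1 by 0.56 ± 0.15 (2 adjusted over the list alone; list adjusted p = 4.17e-06, and adjusted p = 0.185 with an estimated correlation). Atp5a1 lost its call in 9 of 14 fits without 1 array, and Uqcrc1 in 2. Protein secretion fell in 4 of 57 members (6 adjusted over the list alone), with Fkbp2 at -1.29 ± 0.23 (list adjusted p = 0.000109, and adjusted p = 0.286 with an estimated correlation). DNA repair genes fell in 3 of 34 members and rose in 1 (3 and 1 adjusted over the list alone; list adjusted p = 0.036, and adjusted p = 0.42 with an estimated correlation). No ribosome biogenesis gene of 37 passed, over all genes or adjusted over the list alone (0 in limma), but the list median was -0.36 (adjusted p = 0.00171, and adjusted p = 0.291 with an estimated correlation). The B cell identity list did not pass (adjusted p = 0.914, median -0.05), although 3 of 26 members fell and 1 rose, Cd72 by 1.34 ± 0.17. In all, 421 genes rose and 593 fell, 597 of them at least 2-fold, and naive and memory mice differed in age and immunization as well as in cell type.

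Memory against germinal center cells compared the late, resting progeny with the dividing stage. Klf3 rose by 7.36 ± 0.26 (n = 4 and 3, adjusted p = 2.11e-10, limma), Sspn at least 78.2-fold, Cnn3 by 6.60 ± 0.29, Kctd14 at least 56.8-fold, Plac8 by 6.32 ± 0.22 and Pml, which organizes nuclear bodies, by 6.16 ± 0.20. Ncapg fell by 7.05 ± 0.25, the nucleotide reductase Rrm2 by 7.03 ± 0.43, Cdca5 by 6.81 ± 0.31, Rgs13 by 6.74 ± 0.27, the kinetochore gene Cenpe by 6.66 ± 0.28 and Ccnb2 by 6.64 ± 0.27. Bcl2 rose from 33.7 to 1406 (5.38 ± 0.43, adjusted p = 4.7e-07), Irf4 by 3.15 ± 0.31 and Fcer2a by 1.50 ± 0.31. Mki67 fell by 4.90 ± 0.34, S1pr2 by 3.68 ± 0.22, Bcl6 by 2.69 ± 0.24, Fas by 1.74 ± 0.29 and Bach2 by 1.65 ± 0.35, which did not pass as the mean over its probe sets (-0.65, adjusted p = 0.293). Jchain fell by 4.37 ± 0.68.

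Division genes fell from germinal center to memory cells. Of 41 mitosis genes 40 fell (40 adjusted over the list alone; camera adjusted p = 3.88e-43). Of 36 S phase genes 34 fell (36 adjusted over the list alone; list adjusted p = 3.02e-30). DNA repair genes fell in 23 of 34 members (27 down and 1 up adjusted over the list alone; list adjusted p = 5.66e-13), Rad51ap1 by 6.12 ± 0.34 and Chek1 by 5.88 ± 0.19. Germinal center identity fell in 16 of 22 members (17 adjusted over the list alone; list adjusted p = 4.92e-11), Eaf2 by 6.59 ± 0.34 and Gcsam at least 53.7-fold, with Lmo2 against it (1.68 ± 0.22). Oxidative phosphorylation fell in 27 of 40 members (29 adjusted over the list alone), Ndufa5 by 2.15 ± 0.41 and Cox7a2 by 2.07 ± 0.33, for an adjusted p = 2e-09, and adjusted p = 0.0899 with an estimated correlation. The chromatin modifiers Ezh2 and Dnmt1 fell by 3.21 ± 0.20 and 2.76 ± 0.18, and Tet2 rose by 3.08 ± 0.24, but the Polycomb and DNA methylation list had 7 members up and 6 down of 23 and did not pass (adjusted p = 0.708).

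Lists of the resting B cell rose in memory over germinal center cells. Memory markers rose in 15 of 21 members (15 adjusted over the list alone; camera adjusted p = 6.05e-13), with Ccr6 at 5.97 ± 0.25 and Hhex at 5.58 ± 0.38. Mature B cell identity rose in 19 of 26 and fell in 2 (21 and 2 adjusted over the list alone; list adjusted p = 9.52e-13), with Cd55 at 5.19 ± 0.33 and Bank1 at 1.96 ± 0.20. B cell receptor signalling rose in 17 of 30 and fell in 1 (20 and 1 adjusted over the list alone; list adjusted p = 6.17e-11). MHC class II presentation rose in 9 of 15 (9 adjusted over the list alone; list adjusted p = 3.97e-05), with Cd74 at 1.52 ± 0.33 and H2-Ab1 at 1.34 ± 0.21. With the 3' to middle actin ratio (4.63 in memory and 11.3 in germinal center arrays) as a covariate, these genes did not pass (1.41, adjusted p = 0.154, and 0.57, adjusted p = 0.151), nor did Fcer2a (1.62, adjusted p = 0.0765) or Ndufa5 (-1.43, adjusted p = 0.226). Chemotaxis and adhesion rose in 14 of 26 and fell in 1 (14 and 1 adjusted over the list alone; list adjusted p = 1.11e-07), with Gpr183 at 5.99 ± 0.21 and the gut-homing integrin Itgb7 at 4.40 ± 0.28. Interferon response rose in 16 of 33 (18 adjusted over the list alone; list adjusted p = 1.38e-08), with Irgm1 at 4.25 ± 0.20 and Ddx58 at 3.45 ± 0.14. Toll-like receptor signalling rose in 9 of 20 (10 adjusted over the list alone; list adjusted p = 3.74e-06). Quiescence genes rose in 13 of 28 and fell in 3 (14 and 3 adjusted over the list alone), with Klf2 at 4.58 ± 0.30, Txnip at 3.14 ± 0.20 and Cdkn2c at -2.98 ± 0.17, for an adjusted p = 2.98e-07, and adjusted p = 0.0964 with an estimated correlation.

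Further lists passed only with the preset correlation in that comparison. Marginal zone and B1 cell markers rose in 9 of 17 (adjusted p = 0.000138, and adjusted p = 0.0543 with an estimated correlation), immediate early genes in 9 of 32 (adjusted p = 0.000262, and adjusted p = 0.383 with an estimated correlation), and autophagy and lysosome genes in 9 of 27 with 1 down (adjusted p = 0.00148, and adjusted p = 0.116 with an estimated correlation). Adjusted over the list alone the rises were 9, 12 and 10, and the falls 1, 0 and 3. The heat shock gene Hspa1b rose by 4.70 ± 0.76, but its 4 memory arrays ran from 1591 to 9859. In all, 1994 genes rose and 2090 fell, 2458 of them at least 2-fold; the share that rose, 48.8%, was 35.6% with the actin ratio as a covariate.

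**Figure D2:**
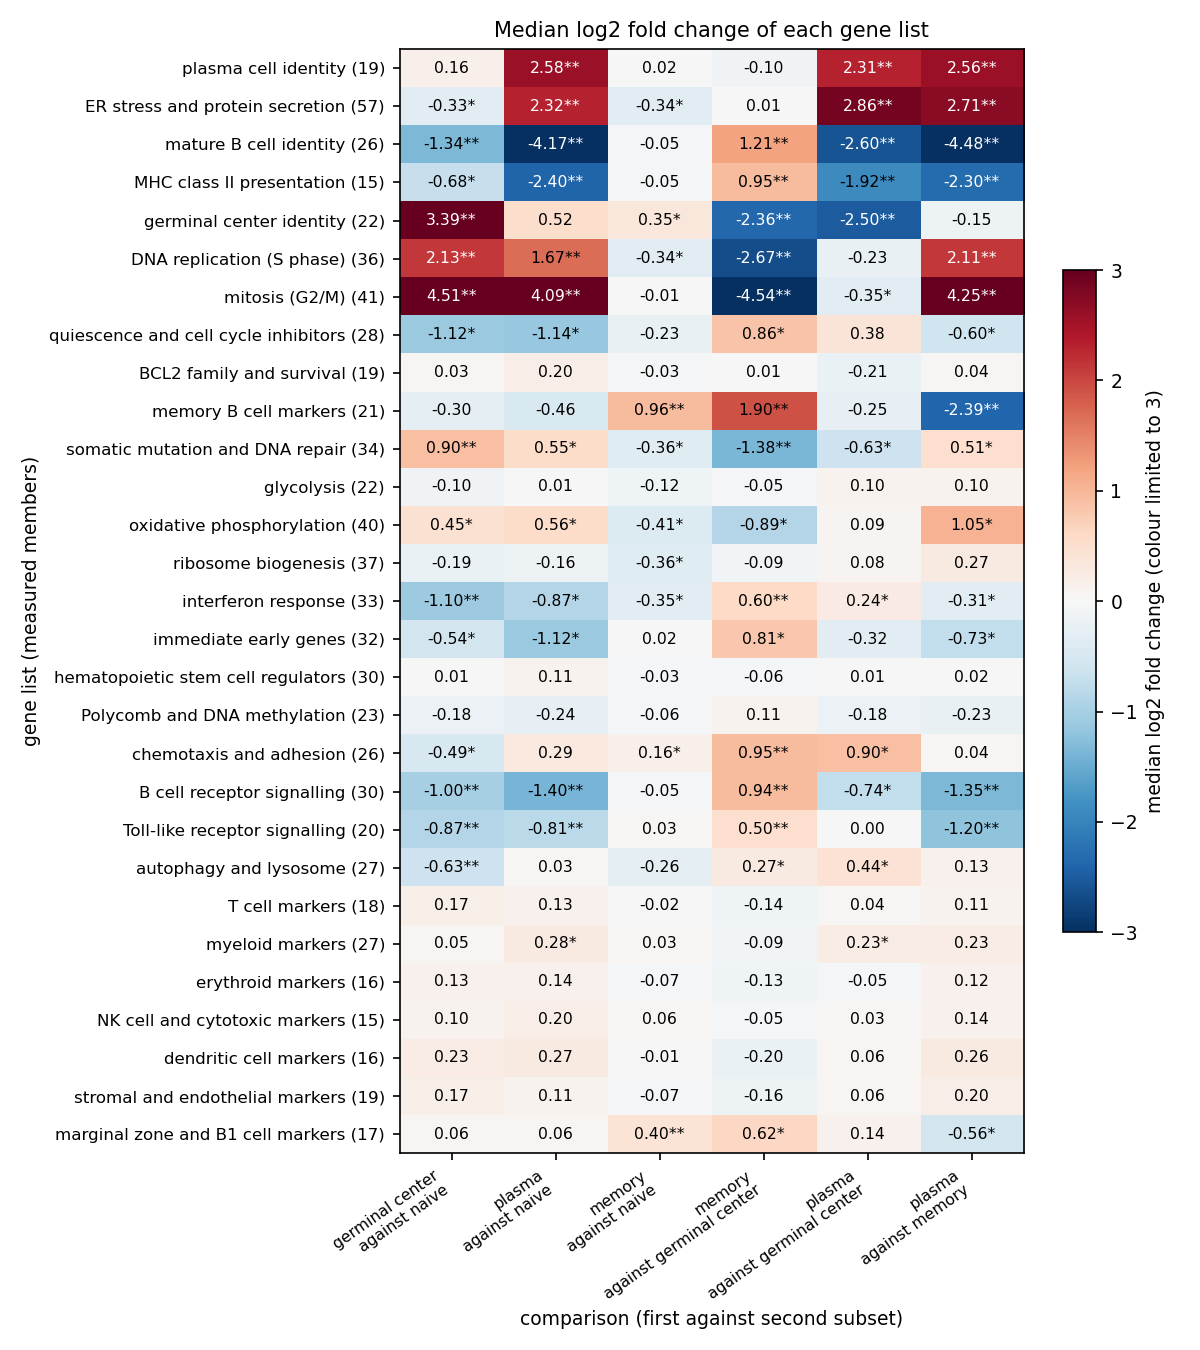
Median log2 fold change of each of 29 gene lists, with the number of measured members, in 6 comparisons of the first subset against the second. One asterisk marks a camera adjusted p under 0.05 with the preset correlation and 2 asterisks the same with the preset and the estimated correlation; the mitosis list runs from -4.54 in memory against germinal center to 4.51 in germinal center against naive.

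Plasma cells differed from germinal center cells in secretion genes. Mki67 did not pass (-0.24 ± 0.34, n = 4 and 3, adjusted p = 0.702, limma), and 32 of 41 mitosis genes did not pass, while 9 fell (9 adjusted over the list alone; list adjusted p = 0.0304, and adjusted p = 0.665 with an estimated correlation). Cenpe fell by 1.85 ± 0.28, but as the mean over its probe sets it did not pass (-1.10, adjusted p = 0.0537). Sdc1 rose at least 188-fold, and Fndc3b and Creb3l2, a factor of the secretory pathway, each at least 123-fold. Bcl6 fell at least 185-fold, Bach2 at least 132-fold and Rgs13 at least 119-fold. Prdm1 rose at least 36.8-fold, and Irf4 and Xbp1 by 5.65 ± 0.31 and 2.56 ± 0.28. Protein secretion rose in 53 of 57 members (53 adjusted over the list alone; list adjusted p = 1.37e-44), with Fkbp11 at least 50.8-fold higher and Hsp90b1 at 5.75 ± 0.42. Plasma cell identity rose in 14 of 19 (16 adjusted over the list alone; list adjusted p = 2.99e-13), with Cd28 at least 56.9-fold higher, Bhlha15 at 6.14 ± 0.23 and Zbtb20 against it (-1.71 ± 0.37). Germinal center identity fell in 19 of 22 members (19 down and 2 up adjusted over the list alone; list adjusted p = 8.76e-16). B cell identity fell in 21 of 26 (24 adjusted over the list alone; list adjusted p = 1.09e-21), with Cd22 at -6.33 ± 0.22, and MHC class II presentation in 10 of 15 (11 down and 1 up adjusted over the list alone; list adjusted p = 3.77e-09), with Cd40 at -6.45 ± 0.34.

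Other lists passed between plasma and germinal center cells only with the preset correlation. DNA repair fell in 16 of 34 members (adjusted p = 0.000393, and adjusted p = 0.184 with an estimated correlation). The S phase list did not pass (11 of 36 members fell and 1 rose, 12 and 1 adjusted over the list alone, median -0.23, adjusted p = 0.0534), and Pold1 fell by 3.87 ± 0.24. B cell receptor signalling fell in 16 of 30 and rose in 5 (adjusted p = 0.000126, and adjusted p = 0.163 with an estimated correlation). Chemotaxis and adhesion rose in 14 of 26 and fell in 5, with Selplg at 5.38 ± 0.31 and Cxcr3 at 3.70 ± 0.38 against S1pr3 at least 127-fold lower (adjusted p = 0.00619, and adjusted p = 0.231 with an estimated correlation). Autophagy and lysosome genes rose in 11 of 27 and fell in 1, with Ctsb at 3.31 ± 0.17 (adjusted p = 0.000636, and adjusted p = 0.0967 with an estimated correlation), and interferon response rose in 8 of 33 and fell in 1 (adjusted p = 0.00978, and adjusted p = 0.244 with an estimated correlation). Myeloid markers rose in 4 of 27 over all genes and 0 adjusted over the list alone (adjusted p = 0.0362, and adjusted p = 0.489 with an estimated correlation). Adjusted over the list alone, 17 DNA repair genes fell and 1 rose, and 17 receptor signalling genes fell and 6 rose. On the same basis 15 chemotaxis genes rose and 5 fell, 11 lysosome genes rose and 1 fell, and 8 interferon genes rose and 1 fell. In all, 2033 genes rose and 2298 fell.

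Plasma and memory cells were the most distant pair by the count of genes called, with 3131 genes higher and 2904 lower in plasma cells. No other pair had 4 arrays on each side. Without memory array 4 the count was 5384, below the 5517 of plasma against naive cells on all arrays. Sdc1 rose by 7.83 ± 0.51 (n = 4 and 4, adjusted p = 2.34e-08, limma), Eaf2 by 7.52 ± 0.31, Rrm2 by 7.49 ± 0.39, Jchain by 7.30 ± 0.63, Prdm1 by 4.69 ± 0.20, Mki67 by 4.67 ± 0.32 and Xbp1 by 2.56 ± 0.26. S1pr3 fell at least 181-fold, and Hhex at least 171-fold. Srpk3 fell by 7.75 ± 0.24, Bcl2 by 6.73 ± 0.40 and Bcl6 at least 28.5-fold. Protein secretion rose in 54 of 57 members (54 adjusted over the list alone; camera adjusted p = 8.63e-31), Fkbp11 by 5.63 ± 0.23 and Ssr2 by 5.16 ± 0.14, with Ddit3 against it (-0.81 ± 0.27). Ddit3 lost its call in 4 of the fits without 1 array. Mitosis rose in 39 of 41 members (39 adjusted over the list alone; list adjusted p = 1.17e-29). S phase rose in 34 of 36 and fell in 1 (35 and 1 adjusted over the list alone; list adjusted p = 2.88e-18). Plasma cell identity rose in 15 of 19 and fell in 1 (15 and 1 adjusted over the list alone; list adjusted p = 1.83e-09). B cell identity fell in 25 of 26 (25 adjusted over the list alone; list adjusted p = 6.79e-28), Cd22 by 7.51 ± 0.21. MHC class II presentation fell in 14 of 15 (14 adjusted over the list alone; list adjusted p = 1.28e-13), Cd40 by 6.96 ± 0.32. Memory markers fell in 16 of 21, Ccr6 by 6.17 ± 0.23 and Nid1 by 4.90 ± 0.28, while Cd44 rose by 1.41 ± 0.23 (16 and 1 adjusted over the list alone; list adjusted p = 2.84e-11). B cell receptor signalling fell in 23 of 30 and rose in 3 (23 and 3 adjusted over the list alone; list adjusted p = 6.05e-13). Toll-like receptor signalling fell in 11 of 20 and rose in 2 (11 and 2 adjusted over the list alone; list adjusted p = 2.34e-05).

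Oxidative phosphorylation rose in 34 of 40 members in plasma over memory cells, Uqcrq by 2.61 ± 0.24 and Atp5b by 2.39 ± 0.26 (34 adjusted over the list alone; adjusted p = 8.87e-09, and adjusted p = 0.098 with an estimated correlation). Cox6a1 fell by 0.31 ± 0.10, but a mean over its probe sets rose by 0.53. DNA repair rose in 18 of 34 and fell in 5 (20 and 5 adjusted over the list alone; adjusted p = 0.000123, and adjusted p = 0.146 with an estimated correlation). Quiescence fell in 13 of 28 and rose in 4 (16 and 6 adjusted over the list alone; adjusted p = 0.000515, and adjusted p = 0.265 with an estimated correlation), and immediate early genes fell in 15 of 32 (16 adjusted over the list alone; adjusted p = 2.34e-05, and adjusted p = 0.307 with an estimated correlation). Of the immediate early genes, Fos and Egr3 read 4395 and 799.2 on memory array 4, against at most 139.6 and 171.7 on the other memory arrays. Interferon response fell in 11 of 33 and rose in 4 (12 and 4 adjusted over the list alone; adjusted p = 0.036, and adjusted p = 0.319 with an estimated correlation), and marginal zone and B1 markers fell in 9 of 17 and rose in 4 (9 and 4 adjusted over the list alone; adjusted p = 0.0394, and adjusted p = 0.282 with an estimated correlation).

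Genes that set each subset apart were higher there than in every other subset by a log2 fold change of at least 1. Germinal center cells had 283 such genes, led by Rgs13, Gcsam, the embryonic globin gene Hbb-bh1, Rassf6, Nrep and Serpinb6b. Hbb-bh1 reached 914.0 there against 14.1 to 22.2 elsewhere, and Hemgn, another erythroid gene, rose by 3.22 ± 0.21 over naive cells. Plasma cells had 740, led by Cd28, Bhlha15, Filip1, Pon3, Fndc3b and Hnrnpll, and they held 52 of 57 secretion genes. Memory cells had 129, led by Sema4f (266.9, against 7.60 in naive cells), the protease regulator Rhbdf1 (1193), Phxr4, the fatty acid receptor Ffar2 (1374), Ahnak and the scavenging receptor Ackr3, and they included the memory markers Nid1 (383.7), Cd80 (67.0) and Pdcd1lg2, these last 3 named after their values were seen. Naive cells had 115, led by Ms4a4c (1695), Tsc22d1, Gpat3, Eps8, Ssbp2 and Ephx1, with 5 interferon genes among them: Ifit2, Oas1a, Oasl1, Usp18 and Rtp4.

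The resting subsets, naive and memory, shared 488 genes that were higher than in both germinal center and plasma cells. Cnn3 (7086 and 3913, against 40.4 and 19.2), Serpinb1a, Hhex, Cd55, the exchange factor Arhgef18 and Ccr6 led this set, which held 16 of 26 B cell identity, 8 of 28 quiescence and 4 of 15 MHC class II genes. In the opposite direction 352 genes were higher in germinal center and plasma cells. Eaf2, Ccnb2, Rgcc, the replication licensing gene Cdc6, Rrm2 and Cdca5 led that set, with 38 of 41 mitosis, 29 of 36 S phase and 12 of 34 DNA repair genes.

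**Figure D3:**
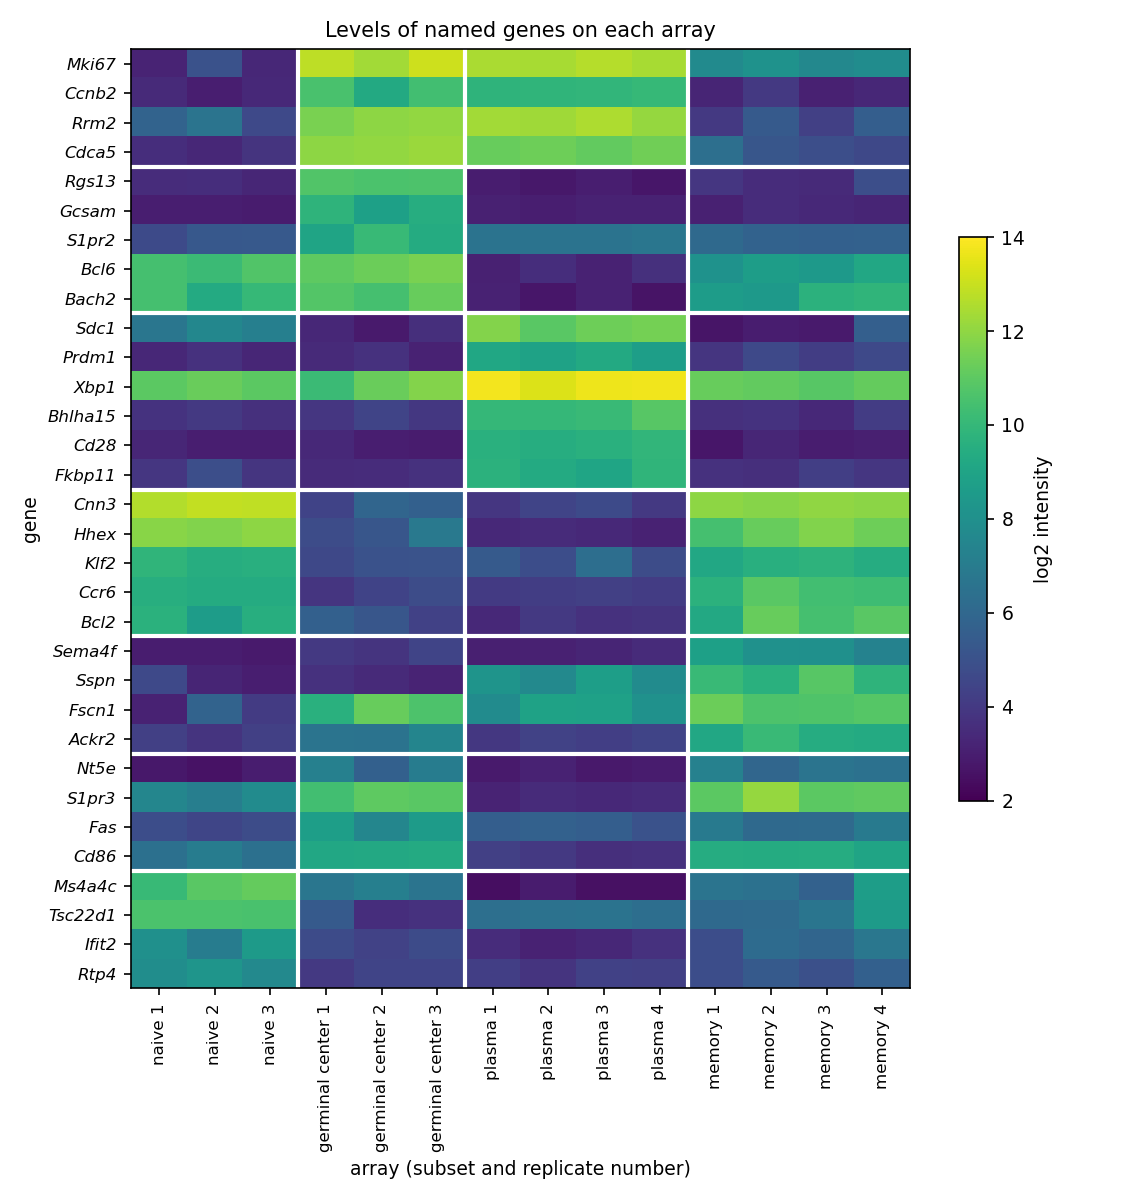
Log2 intensity of 32 named genes on each of 14 arrays, ordered by subset and replicate, with white lines between subsets and between groups of genes. Mki67 reads 5180 to 8589 on the germinal center arrays and 197 to 282 on the memory arrays.

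Several lists of other cell types, myeloid markers excepted, and some further lists did not pass in any comparison. The smallest camera adjusted p over the 6 comparisons was 0.448 for T cell markers, 0.351 for NK cell markers, 0.0501 for dendritic cell markers, 0.364 for stromal markers and 0.134 for erythroid markers. It was 0.371 for glycolysis, 0.118 for BCL2 family and survival, 0.635 for hematopoietic stem cell regulators and 0.0828 for Polycomb and DNA methylation. Cd38 and Ighd, used in the sort, are not analysed here because the annotation names no probe set for them.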

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

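The tests of Hbb-bh1, of the interferon list and of Mki67 below, and the splits for genes shared by germinal center and memory or by naive and plasma cells, were chosen only after the results were seen; the other splits of the arrays and the search for outlying arrays were planned.

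Hbb-bh1, an embryonic beta globin gene, was read at 766.3 or more on every germinal center array and at 29.1 or less on the other 11 arrays. A fault of 1 probe set is argued against, since all 3 Hbb-bh1 probe sets rose, the least by 2.98 ± 0.14. Erythroid cells or blood RNA in the germinal center sort cannot be told apart from expression in B cells: of 8 adult globin probe sets, each compared with itself, 1 rose (1.33 ± 0.25; 59.1 to 124.2 on germinal center and 23.8 to 45.4 on other arrays), 1 fell and 6 did not pass, and most read near background. The gate against Ter119 would remove erythroid cells, and of 15 erythroid list members besides Hemgn 1 was higher and 1 lower. Expression of Hbb-bh1 in germinal center B cells may explain the pattern as a hypothesis, while an unrelated transcript shared by the 3 probe sets was not tested.

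The interferon list was lower than in naive cells in germinal center (23 of 33 members fell), plasma (20 fell, 5 rose) and memory cells (6 fell), but with an estimated correlation it did not pass in plasma (adjusted p = 0.0653) or memory cells (adjusted p = 0.0553). A shift of all genes of similar brightness is argued against: among 10000 random lists matched on mean level, the list's median lay at percentile 0.01 in germinal center and plasma cells, the smallest these lists can give, and at 0.08 in memory cells. A single naive array is argued against for germinal center and plasma cells, where the list's median stayed 0.787 and 0.508 below that of bright genes (differences of -0.787 and -0.508) without the naive array whose absence raised it most. For memory cells that difference was -0.124 without naive array 2, -0.134 without naive array 1 and -0.19 without naive array 3. With all arrays the list's median was -0.35 and that of bright genes -0.205. With each array scored by the list's median against bright genes, every naive array lay above every memory array. The lowest naive array lay only 0.06 above the highest memory array, where the SD within the 2 subsets was 0.11. With a gap inside that spread, a single naive array cannot be told apart from a subset difference. Age, immunization and cell type differ together between these mice, and each may account for the pattern, untested.

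Mki67 rose in memory over naive cells to 3.13% of its rise in germinal center and 3.70% of its rise in plasma cells. Cells of either kind carried past the gates of the memory sort would bring other mitosis genes in that share. Over the 13 of 40 bright enough in germinal center cells, however, the upper quartile of their share was 0.272% (median -0.0613%). For plasma cells 8 were bright enough, with an upper quartile of 0.441% (median 0.134%); the highest shares were 6.58% (Smc4) and 1.84% (Hmmr). Both sources are therefore argued against as the whole cause, Smc4 excepted. A low level of Mki67 RNA in memory cells may remain, as a hypothesis, but Mki67 has a single probe set here, and a signal specific to it was not tested.

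Some arrays stood far from the other 3 of their subset, by the gap to the nearest array over the range of the subset. Among 168 searched, 7 did. Chance alone gives about 1 in 20, so 7 is no more than chance would give and no array is singled out by it. Memory array 2 was high for Cxcr3 (673.2, ratio 0.95) and S1pr3 (4347, ratio 0.903) and low for Lmo2 (4962, ratio 0.885). Memory array 4 was high for Sdc1 (49.9, ratio 0.894). Plasma array 2 was low for Tent5c (3950, ratio 0.842) and Ighm (14590, ratio 0.836), and plasma array 4 was high for Bhlha15 (1872, ratio 0.849). Among genes looked at after their values were seen, memory array 4 also had Fos at 4395 and Hspa1b at 9859, plasma array 3 had Fos at 3992, and naive array 1 had Hspa1b at 3735.

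Other splits of the same arrays were fitted in the same model to ask whether an arbitrary grouping of arrays gives such counts. For genes called, an arbitrary grouping is argued against in 5 comparisons. There the real split was the 1 split of 35 with a count as large. That share is the smallest that 35 splits can give, and it was not adjusted over the comparisons. The highest other counts were 1564 against the real 5517 for plasma against naive, 160 against 1014 for memory against naive, 678 against 4084 for memory against germinal center, 1039 against 4331 for plasma against germinal center, and 0 against 6035 for plasma against memory. Germinal center against naive has 10 splits, too few for a share under 0.05; the real count was 3542 genes and 15 lists and the highest other 1 gene and 14 lists. For the numbers of gene lists in the other 5 comparisons the real split did not give the largest count. At least as many lists as the real 14, 10, 16, 12 and 15 were called in 7, 5, 5, 8 and 8 of 35 splits for plasma against naive, memory against naive, memory against germinal center, plasma against germinal center and plasma against memory. The highest others were 17, 11, 18, 16 and 17. Other splits can keep part of the difference between subsets, so these counts do not show how many genes or lists chance alone would call. A count of lists called at the preset correlation says little by itself, and the sizes and member counts of each list carry the result.

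For genes that set subsets apart, the real grouping was the 1 with a count as large among 100 groupings of the 14 arrays in every case. An arbitrary grouping is argued against here too. These groupings also mix subsets, so the same limit holds. The highest other counts were 37 against 115 for naive, 1 against 283 for germinal center, 0 against 740 for plasma and 50 against 129 for memory cells. For naive and memory against the rest it was 0 against 488, for germinal center and plasma 0 against 352, for germinal center and memory 0 against 49, and for naive and plasma 0 against 28.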

How the results depend on the processing

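The actin ratio as a covariate, centring on bright genes, and leaving out germinal center array 1 with memory array 4 were tests chosen only after the results were seen. Of 516 recomputed counts 479 stayed within 1.5 times the reported count. Of 6551 recomputed fold changes of named genes 6425 kept their direction and side of the threshold, 122 lost and 3 gained a call, and 1 reversed. Reversed was Cox6a1 in plasma against memory cells, at 0.53 as a mean over its probe sets. With every probe set as its own unit, the calls became 6178, 10355, 1772, 8162, 7824 and 12781 for germinal center, plasma and memory against naive, memory against germinal center, plasma against germinal center and plasma against memory, because more units were tested. The genes set apart became 194 in naive, 481 in germinal center, 1366 in plasma and 336 in memory cells, 907 in naive and memory and 559 in germinal center and plasma cells. As a mean over probe sets they were 75 in naive, 174 in germinal center and 79 in memory cells; the cause was not tested. Stricter thresholds call fewer by construction: in the order above, 2256, 3393, 597, 2458, 2727 and 3596 genes passed with at least 2-fold, and 2258, 442 and 2661 passed at an adjusted p under 0.01 for germinal center against naive, memory against naive and memory against germinal center. Lists called with an estimated correlation fell to 9, 8, 2, 5 and 9 for germinal center, plasma and memory against naive, plasma against germinal center and plasma against memory. A floor of 16 before log2 left 596 genes in memory against naive; the cause was not tested. With the actin covariate 1540 genes were called for germinal center against naive and 1779 for memory against germinal center, with 69 set apart in memory and 239 in naive and memory cells. The covariate differs along with the subset, and the cause was not tested. It ended 12 named calls, 8 in germinal center against naive, among them H2-Ab1, Lmo2 and Egr3, and 4 in memory against germinal center (Fcer2a, H2-Ab1, Cd74 and Ndufa5). Centring on bright genes left 74 genes set apart in naive cells; the cause was not tested. With 1 array left out, genes called in memory against naive ranged from 603 (without naive array 2; 624 without naive array 3) to 1273 (without germinal center array 1). Leaving out 1 array changed 13 named calls. Ptprc, Itga6 and Bcl6 in germinal center against naive, Fcer2a, Atp5a1, Prdm1, Jchain, Uqcrc1 and Ifit2 in memory against naive, Csf1r in plasma against naive, and Ddit3 and Cox6a1 in plasma against memory lost theirs, with adjusted p up to 0.181 (Ptprc without germinal center array 2). Bcl2 in memory against naive passed without memory array 1 (1.59, adjusted p = 0.0189). Same-numbered arrays of different subsets did not pair: 6 of 19 such pairs had residual r above 0.1, with a median of -0.0102 against -0.00452 for other pairs. A replicate block left every count within 1.5 times. It ended the calls of Ptprc and Itga6 in germinal center against naive and of Fcer2a and Atp5a1 in memory against naive cells. Without the dimmest genes 1 named fold change had no value.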

Other observations

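The sharing of genes by germinal center and memory cells, and by naive and plasma cells, was examined only after the results were seen. Germinal center and memory cells shared 49 genes that were at least 2-fold higher than in both naive and plasma cells. They were led by Nt5e (101.0 and 95.5, against 6.81 in naive and 7.67 in plasma cells), Lmo7, Parm1 (279.0 and 207.3, against 13.4 and 18.7), S1pr3 (1742 and 2484, against 178.5 and 10.4), Bmpr1a (242.9 and 231.6, against 14.3 and 24.7) and Ackr2, and included Cd86 (606.8 and 638.4, against 99.7 and 15.0). Naive and plasma cells shared 28 genes, led by Sdc1 (142.3 and 2657, against 9.71 in germinal center and 11.7 in memory cells), Itm2a, Ggh, Ctnna1 (974.9 and 392.8, against 74.2 and 61.5), Tubb2b and Hsd11b1. Measures of RNA quality and of array signal also differed between subsets. The ratio of 3' to middle GAPDH signal was 6.91 ± 1.2 in plasma and 10.6 ± 1.3 in naive arrays (SD, n = 4 and 3). It was 9.40 ± 1.3 in germinal center and 12.0 ± 0.97 in memory arrays (SD, n = 3 and 4), unlike the actin ratio, which was highest in germinal center arrays. Plasma array 1 had an 18S ribosomal RNA signal of 4935, against 294.5 to 899.6 on the other plasma arrays. The signal of the spiked-in bacterial control BioB averaged 693.6 on naive arrays (444.1 to 1021) and 199.4 on plasma arrays (131.4 to 357.9). It averaged 418.8 on germinal center and 336.8 on memory arrays. How this difference bears on the fold changes was not tested.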
